A study of Rattus norvegicus with 20 samples.

How the data were processed

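RNA sequencing had been done on lung tissue of 20 rats, 1 library per animal, in 4 groups of 5. The groups were Sham (abdominal surgery without caecal injury), CLP (caecal ligation and puncture, an operation that releases gut bacteria into the abdomen and is used as a model of sepsis and acute lung injury), Sham+VNS and CLP+VNS, where VNS is electrical stimulation of the right vagus nerve in the neck. Groups and replicate numbers were taken from the sample labels. The replicate numbers of the CLP libraries were 1, 3, 4, 5 and 6 and those of the CLP+VNS libraries 1, 3, 5, 8 and 11. The sources used here do not give the time between surgery and tissue collection for each library, the day of collection, the sequencing batch or the sex of single animals, and they do not state that equal numbers pair the animals.

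The authors deposited a table per gene and a table per transcript, each with a value for every library. Per the file headers, the tables hold FPKM values and TPM values calculated by the authors, both scaled for transcript length and library size. The authors also deposited read counts, which are expected counts (estimated counts) not scaled between libraries: 91.5% of the gene values are whole numbers and the others carry decimals. A further set of deposited columns holds a normalized signal, read counts times 1 factor per library, and how the authors made these factors is not given in the sources used here. Group averages of the FPKM, TPM, count and signal columns were also deposited and were not used here. Per the submitters' processing notes the reads were aligned to the rat assembly mRatBN7.2; the aligner, the counting program and the annotation release are not given in the sources used here. How reads shared by near-identical genes were divided is therefore unknown, and values of gene families such as Reg3, the RT1 class II genes, Ifitm6, the haemoglobin genes and ribosomal protein genes with retained copies are uncertain in that respect.

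The estimated counts per gene, rounded to whole numbers, were the input of all gene tests. The table held 19060 genes. Of their identifiers, 18800 were found in the rat reference table of assembly GRCr8, which was used for gene names and gene types only, and 18498 of those are protein-coding. Because that assembly differs from mRatBN7.2, no coordinates are given. Total counts per library ran from 13729654 to 14453188. A gene with 0 counts over the 5 libraries of a group was given a floor of 3 counts over the group, and folds against such a group are written as lower bounds. Where a group had 1 to 3 counts, the ratio of summed counts is given with its 95% Clopper-Pearson interval. Such intervals and floors cover counting error only. Gene levels are given in CPM, counts per library total on the usual scale, with the total multiplied by its TMM factor, as mean ± SD over the 5 animals of a group, and log2 fold changes as estimate ± SE.

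Genes were kept with edgeR's filterByExpr at a minimum count of 10 in about 5 libraries, which left 14794 genes. Libraries were scaled with TMM. The 4 group means were fitted to all 20 libraries with edgeR's quasi-likelihood model (robust estimation, 16 residual degrees of freedom, common biological coefficient of variation 0.161) and 5 comparisons were tested: CLP against Sham, CLP+VNS against CLP, Sham+VNS against Sham, CLP+VNS against Sham+VNS, and the interaction, which is the CLP+VNS against CLP difference minus the Sham+VNS against Sham difference. All tests were two-sided. Adjusted p-values of genes are from edgeR with Benjamini-Hochberg adjustment over the tested genes of a comparison, and a gene was called at an adjusted p below 0.05. The fitted log2 fold changes use a prior count; values drawn per library used a prior count of 2. Il6 and Il10 did not reach the count filter and were compared by exact two-sided permutation tests of the mean CPM, adjusted over their 8 tests.

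Of 46 gene lists with 742 members fixed before the data were examined, 717 members were in the table, 2 of them by an older symbol, and 649 were tested. The 43 lists with at least 4 tested members were compared with all other genes by camera from limma with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes. Members called are counted over all genes tested and adjusted over the list alone; where a single count is given beside a list, both counts were equal or the text says which is given. The lists overlap, for example in Hp, Cebpd, Dusp1, Mt2A and Pdk4. A list score is the mean log2 CPM of a list's tested members in a library.

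Named genes followed a rule fixed before the data were examined. It takes, per comparison, the 10 highest and 10 lowest fold changes among called genes with a mean of at least 1 CPM, an established symbol and no overlap between the 5 libraries of each group (no overlap was not asked for the interaction). Where no gene passes, it takes the 5 smallest p-values, given as not past the threshold. It adds a panel of 15 genes in every comparison and up to 4 members of each list discussed, those with the smallest adjusted p. Further genes named beside a count of 5 or fewer list members, or as set apart in a library, were chosen after their values were seen. The slope between the CLP effects with and without stimulation was fitted by total least squares over all tested genes, with a jackknife SE over libraries. For the comparison of the CLP effect with the stimulation effect in CLP animals, which share the CLP libraries with opposite signs, unchanged and CLP-only groups were simulated and the CLP libraries were divided between the comparisons, with 20 runs of each.

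The alternatives chosen before the data were examined were other scaling factors (DESeq2's, upper quartile and total count alone), no count filter or a filter of at least 1 CPM in 5 libraries, a surrogate variable from sva, DESeq2, limma with voom and sample quality weights, a fit of the compared groups alone, replicate number as a block, the deposited FPKM on a log2 scale with pseudocounts of 1 and 0.1, a fold threshold, and leaving out each library in turn. Leaving out the 4 sham-operated libraries with Adipoq above 5 CPM was added after seeing the data. Transcript counts were tested with edgeR in the same way. The code was tested on simulated counts with 200 genes changed by known folds. For CLP+VNS against CLP, on 14714 simulated genes, edgeR recovered 65.7% of 1.5-fold, 88.1% of 2-fold and 98.5% of 4-fold changes with 7 false calls among 175. In the same simulation DESeq2 made 26 false calls among 200 and limma 6 among 171. The interaction test recovered 43.3%, 76.1% and 87.9% on 14703 simulated genes. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and, for data.table, version 1.17.8. No reads, genome or other assay were analysed here.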

Results

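Lung RNA was sequenced from 20 rats in a design that crossed the operation, sham or CLP, with stimulation of the right vagus nerve in the neck (VNS), with 5 animals in each of the 4 groups. Total counts per library ran from 13785062 to 14186121 in Sham, 13869123 to 14453188 in Sham+VNS, 13806220 to 14327215 in CLP and 13729654 to 14275406 in CLP+VNS. At this depth 3 counts over a group corresponded to 0.0423 CPM in Sham, the level under which a gene with no counts there could not be seen. The first principal component of the 1000 most variable genes held 46.8% of their variance and parted the CLP-operated from the sham-operated animals. Its group means were -27.4 in Sham, -23.0 in Sham+VNS, 23.1 in CLP+VNS and 27.4 in CLP. The second held 8.69% and the third 6.27%. Sham replicate 1 stood apart on the second component, at 39.0, and had the highest level of the adipocyte gene Adipoq, 285 CPM. Between libraries of a group Spearman's correlation across genes was 0.974 to 0.993.

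**Figure D1:**
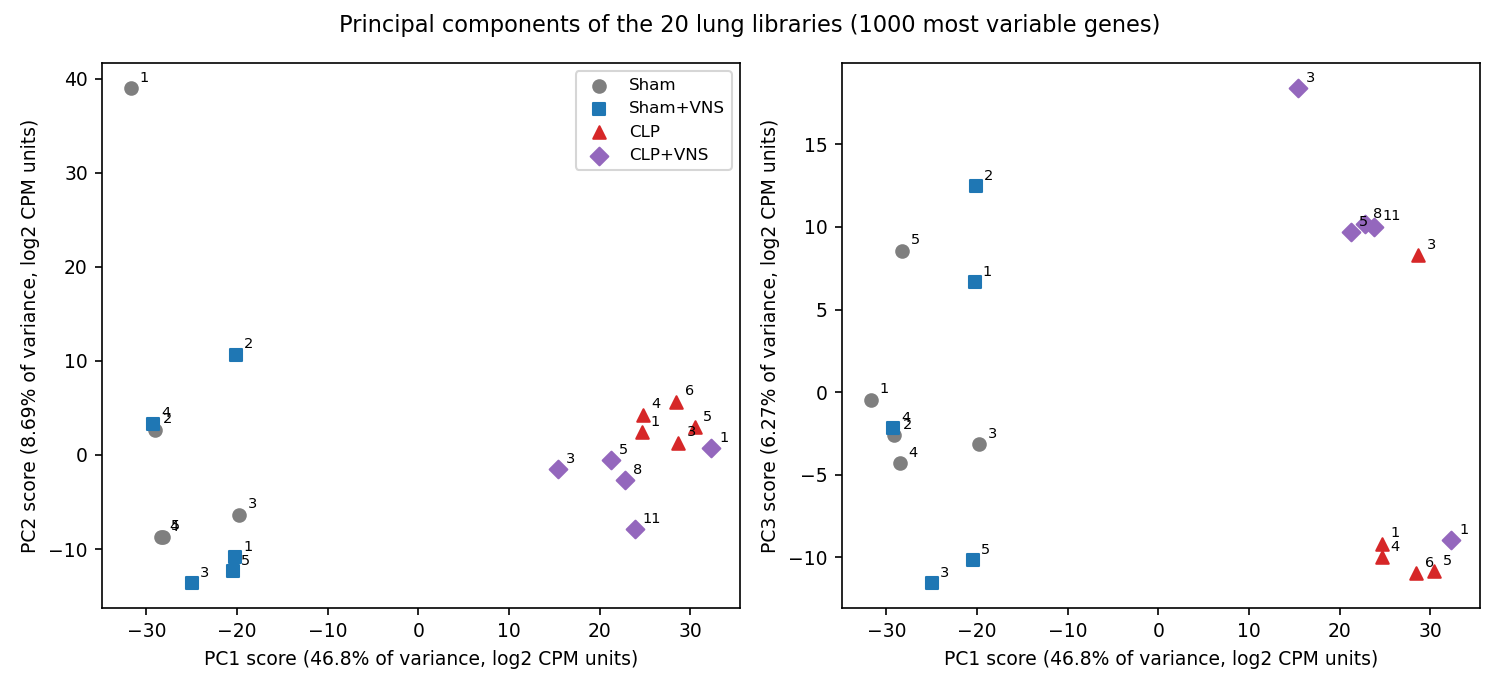
Principal component scores of the 20 libraries from log2 CPM of the 1000 most variable genes, with each point 1 library coloured by group; the axes give the component and its share of variance. The first component (46.8%) holds group means of -27.4 for Sham and 27.4 for CLP, and Sham replicate 1 sits at 39.0 on the second (8.69%).

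The comparison of CLP with Sham describes the lung after caecal ligation and puncture without stimulation. Reg3g, Reg3a and Reg3b, secreted C-type lectins that act against bacteria, were at or near 0 in Sham and reached 37.2 ± 16.2, 8.68 ± 3.79 and 11.2 ± 5.96 CPM in CLP (mean ± SD, n = 5 per group). The ratio of summed counts was 1318 for Reg3g (95% interval 364 to 10885) and 794 for Reg3b (142 to 31414), and Reg3a was at least 205-fold higher. Reads can be shared among these 3 related genes, so their single values are uncertain. Orm1, an acute phase plasma protein, rose from 0.387 ± 0.527 to 30.9 ± 3.37 CPM, and Fga, the fibrinogen alpha chain, rose by 6.34 ± 0.90 on the log2 scale. Saal1 rose from 1.64 ± 0.864 to 161 ± 49.8 CPM. Cxcl2, a neutrophil chemoattractant, rose by 5.76 ± 0.44, Ngp, a neutrophil granule protein, by 5.57 ± 0.84, and Ifitm6, of the interferon-induced transmembrane family, by 5.21 ± 0.37. Wfdc18, of the whey acidic protein family, had a ratio of 108 (29.6 to 899). Without single libraries Ngp stood at 4.68 (without CLP replicate 3), Fga at 7.92 (without Sham replicate 1) and Orm1 at 7.54 instead of 6.31 (without Sham replicate 3). The fitted changes of Wfdc18 and Reg3b, which depend on the prior count, were also higher without Sham replicate 1 and Sham replicate 3 (8.43 instead of 6.37, and 10.3 instead of 8.93). The adjusted p-values of these 10 genes ran from 2.72e-08 (Ifitm6) to 4.47e-05 (Ngp). Their deposited gene identifiers are 24620 (Reg3g), 171162 (Reg3a), 24618 (Reg3b), 687992 (Saal1), 171059 (Wfdc18), 361969 (Fga), 24614 (Orm1), 114105 (Cxcl2), 301026 (Ngp) and 309104 (Ifitm6).

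Among the 10 genes that fell most under the naming rule, Cntn2, an adhesion molecule of neurons, went from 34.5 ± 6.74 to 2.80 ± 1.17 CPM (log2 change -3.62 ± 0.30, adjusted p = 7.99e-08). Hsd11b2, the enzyme that inactivates corticosterone, changed by -4.15 ± 0.72 (adjusted p = 0.000156). Esr1, the estrogen receptor alpha, changed by -3.63 ± 0.56, Adh7, an alcohol and retinol dehydrogenase, by -3.62 ± 0.67, and Mybpc1, a myosin binding protein of slow muscle, by -4.90 ± 0.76. The other 5 were Tm4sf4 (-5.93 ± 1.27), Syt6, a synaptotagmin (-5.24 ± 0.69), Cpvl, a carboxypeptidase (-3.95 ± 0.43), Fam151a (-3.56 ± 0.60) and Krt76, a keratin (-3.22 ± 0.37). In Sham replicate 1 alone Tm4sf4 reached 37.8 CPM, Mybpc1 10.1 CPM and Esr1 15.3 CPM, each set apart from the other Sham libraries, and without it their log2 changes were -4.63, -4.09 and -2.89. Mybpc1 stood at -5.52 without CLP replicate 6, Adh7 at -4.25 without CLP replicate 1 and Hsd11b2 at -4.91 without CLP replicate 4, all still called. Their identifiers are 25356 (Cntn2), 25117 (Hsd11b2), 24890 (Esr1), 171178 (Adh7), 362867 (Mybpc1), 116467 (Tm4sf4), 60565 (Syt6), 502774 (Cpvl), 313430 (Fam151a) and 407757 (Krt76).

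Innate immune genes rose together. Of the 28 tested genes of the NF-kappaB and Toll-like receptor list, 23 rose and 1, the adhesion receptor Icam1, fell, with a median log2 change of 0.88. They included Zc3h12a, an RNase that limits cytokine messages (1.59 ± 0.10), the NF-kappaB inhibitor Nfkbia (1.05 ± 0.15), Nfkbiz (1.19 ± 0.10) and Bcl3 (1.59 ± 0.14). Of 23 cytokine and chemokine genes 17 rose and 1, the alarmin Il33, fell (median 1.06), among them Tnf (2.73 ± 0.25, adjusted p = 1.93e-07), Il1a (2.19 ± 0.21), Cxcl1 (3.22 ± 0.35), Ccl2, a monocyte chemoattractant (2.35 ± 0.34), and Il1b (1.06 ± 0.22). Of 19 acute phase and host defence genes 18 rose and none fell (median 2.83), with Cp, the copper carrier ceruloplasmin (1.07 ± 0.09), the lipopolysaccharide binding protein Lbp (2.83 ± 0.24), haptoglobin, Hp (3.08 ± 0.29), and Lcn2, an iron-siderophore binder (3.81 ± 0.80). The camera adjusted p-values of these 3 lists with an estimated correlation were 0.00271, 0.00271 and 0.0116. Genes of the glucocorticoid response also rose, 14 of 16 against 2 lower, with Fkbp5, a receptor co-chaperone (2.01 ± 0.29), Cebpd (1.54 ± 0.15) and Pdk4 (2.32 ± 0.23), while the receptor gene Nr3c1 fell (-0.41 ± 0.04). Hypoxia and glycolysis genes rose in 13 of 19 cases (14 adjusted over the list alone) and fell in 1, with the glucose transporter Slc2a3 higher (2.59 ± 0.24) and Vegfa lower (-0.89 ± 0.10). In the coagulation list 7 of 17 rose and 2 fell, with the urokinase receptor Plaur (1.49 ± 0.17) and tissue factor, F3 (0.74 ± 0.07). In the apoptosis list 5 of 15 rose, with Cdkn1a, a cell cycle inhibitor (2.37 ± 0.16), and Mcl1 (0.69 ± 0.07). These last 4 lists held with an estimated correlation at adjusted p = 0.0496 each.

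**Figure D2:**
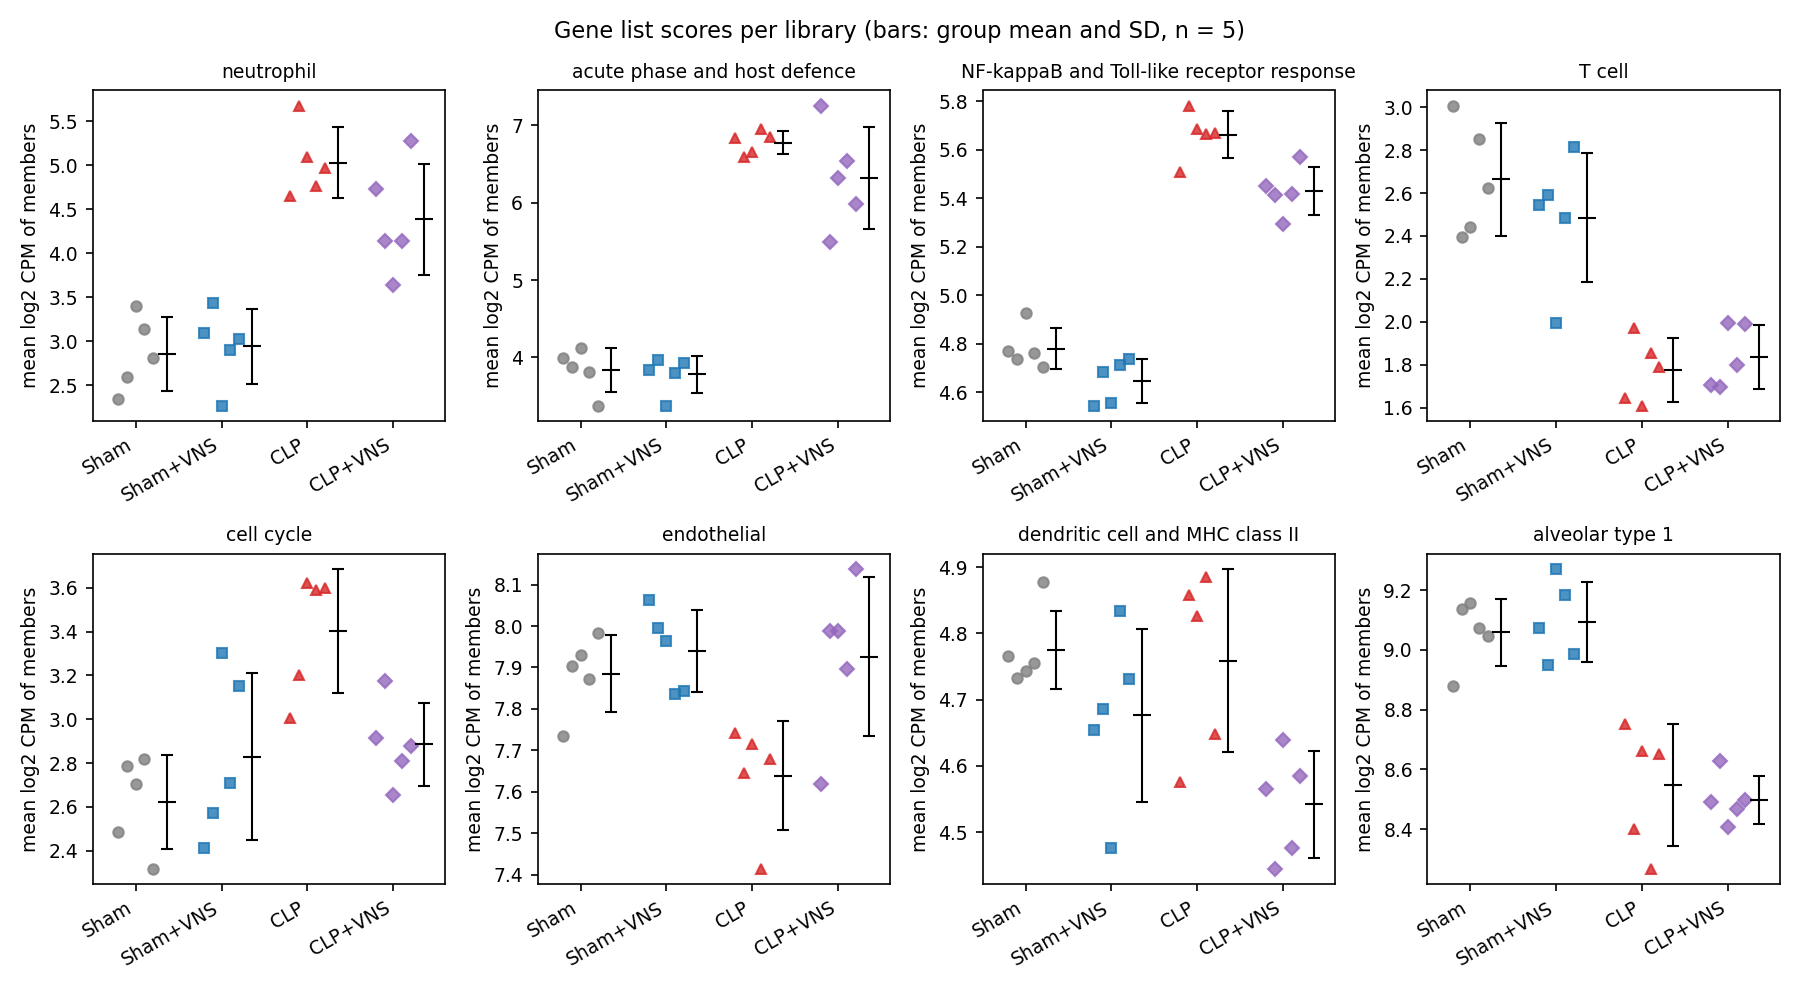
Scores of 8 gene lists per library, the mean log2 CPM of each list's tested genes, by group; points are libraries (5 per group) and bars the mean ± SD. The neutrophil and acute phase panels set both CLP-operated groups above both sham-operated ones, with median log2 changes of 2.53 and 2.83 for CLP against Sham.

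Markers of blood leukocytes moved in opposite directions by lineage. Of 22 neutrophil genes 19 rose and 1 fell, with a median of 2.53. The calcium-binding proteins S100a8 and S100a9 rose by 3.42 ± 0.33 and 2.74 ± 0.29, S100a8 from 115 ± 55.8 to 1229.8 ± 259 CPM, and the formyl peptide receptor Fpr2 by 2.78 ± 0.32, while Retnlg fell (-1.41 ± 0.40). Of 17 monocyte and macrophage genes 9 rose and none fell, with Adgre1 (2.57 ± 0.24), Itgam, an integrin of myeloid cells (2.10 ± 0.25), and the lipopolysaccharide co-receptor Cd14 (1.40 ± 0.14). Complement genes rose in 11 of 19 cases, with C3ar1 (1.38 ± 0.14) and C3 (1.45 ± 0.20). T cell genes fell in 12 of 15 cases and rose in none, with the receptor chain Cd3e (-1.41 ± 0.20), the kinase Lck (-1.10 ± 0.15) and Tcf7 (-1.10 ± 0.15). B and plasma cell genes fell in 6 of 13, with Cd79a (-1.24 ± 0.22), and interferon response genes in 12 of 30 (13 adjusted over the list alone), with Gbp5 (-0.97 ± 0.15) and Ifi44 (-0.73 ± 0.12). Camera with the preset correlation called all 6 lists (adjusted p 8.76e-13 for neutrophil, 0.000439 for monocyte, 2.56e-05 for complement, 2.04e-05 for T cell, 0.0177 for B cell and 0.00279 for interferon genes). None of the 6 held with an estimated correlation (adjusted p = 0.140, 0.153, 0.140, 0.169, 0.447 and 0.555, in that order).

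Structural lung cells showed falls in alveolar type 1, endothelial and mural markers. Of 15 alveolar type 1 genes 10 fell and none rose (1 rose adjusted over the list alone), with the water channel Aqp5 (-1.80 ± 0.21), Gprc5a (-0.72 ± 0.11) and Ager, the receptor for advanced glycation end products (-0.44 ± 0.12, adjusted p = 0.00764). Endothelial genes fell in 10 of 22 cases and rose in 3, with the growth factor receptor Kdr (-1.25 ± 0.15) and the apelin receptor Aplnr (-1.13 ± 0.13) lower and Nos3, Ednrb and Cldn5 higher (the nitric oxide synthase Nos3 0.89 ± 0.13). Pecam1 was not called (-0.18 ± 0.11, adjusted p = 0.209), nor was the surfactant protein gene Sftpc (0.05 ± 0.12, adjusted p = 0.775). Smooth muscle and pericyte genes fell in 5 of 12, with Pdgfrb (-0.64 ± 0.09) and Acta2 (-0.81 ± 0.19), and adrenergic and neuropeptide genes fell in 7 and rose in 1 of 17, with the adrenoceptor Adrb1 lower (-1.37 ± 0.20). With an estimated correlation these 4 lists gave adjusted p = 0.266, 0.555, 0.447 and 0.266. Cell cycle genes rose in 15 of 20 and fell in 1, with the mitotic kinase Aurka (0.90 ± 0.12) and the cyclin Ccnb1 (1.36 ± 0.26), at adjusted p = 0.358 with an estimated correlation. Immediate early genes rose in 9 of 17 (Junb 1.18 ± 0.12, Fos 1.29 ± 0.17), unfolded protein genes in 10 of 16 (12 adjusted over the list alone; Hspa5 1.12 ± 0.16), and inflammasome genes in 6 of 13 (Txnip 0.56 ± 0.10). Ferroptosis and iron genes rose in 10 and fell in 3 of 15 (Acsl4 0.89 ± 0.12), and NRF2 and oxidative stress genes rose in 8 and fell in 4 of 20, with the superoxide dismutase Sod2 higher (2.44 ± 0.13) and Sod3 lower (-1.11 ± 0.13). These 5 lists were called with the preset correlation and gave adjusted p = 0.0848, 0.169, 0.221, 0.105 and 0.140 with an estimated correlation. The median of the NRF2 list, 0.01, became -0.04 when libraries were scaled by total count alone, and was just below 0 without Sham replicate 2 or CLP replicate 1 or 5 (-0.00922, -0.0168 and -0.00420).

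Lists that camera did not call in CLP against Sham nevertheless held changed members. Of all tested genes 40.3% were called in this comparison, so a share of members near or below that is no finding about a list. In the circadian clock list 6 of 17 rose and 7 fell, with the activators Clock (0.46 ± 0.06) and Arntl (2.10 ± 0.31) higher and the output genes Dbp (-2.87 ± 0.59) and Hlf (-1.25 ± 0.25) lower. The labels give no hour of collection, so for these genes a difference in hour cannot be told apart from an effect of CLP. Per1 was called (0.41 ± 0.14, adjusted p = 0.0242), but lost the call without Sham replicate 1, 4 or 5 or CLP replicate 1 or 3 (adjusted p 0.0542, 0.0647, 0.0554, 0.0534 and 0.0532; 0.00509 to 0.0647 over its alternatives). Fibroblast and matrix genes rose in 4 and fell in 11 of 16, with the protease inhibitor Timp1 higher (4.04 ± 0.33) and the matrix protein Postn lower (-1.34 ± 0.20). In the cholinergic list 4 of 10 rose and 2 fell (4 fell adjusted over the list alone). Chrna7, the alpha7 subunit of the nicotinic acetylcholine receptor, rose (1.84 ± 0.38, adjusted p = 0.000753; 0.522 ± 0.184 to 1.89 ± 0.820 CPM), as did Jak2 (0.76 ± 0.10) and Stat3 (0.72 ± 0.07), while Chrna4 fell (-1.64 ± 0.37). That list's median (-0.09) and mean (-0.17) were negative while camera's direction was up. In the dendritic cell and MHC class II list 4 of 17 rose (RT1-Bb, RT1-DMa, RT1-DMb and Clec9a) and 2 fell (Ciita and Ccr7), with a median of -0.04 and camera's direction up. Of these, RT1-Bb lost its call without Sham replicate 1, 2, 3 or 5 or CLP replicate 3 or 4 (adjusted p 0.0543 to 0.0978; 0.00289 to 0.101 over its alternatives), Clec9a without Sham replicate 1 or 4 or CLP replicate 5 (0.0575 to 0.0655; 0.00158 to 0.123) and Ciita without Sham replicate 2, 4 or 5 or CLP replicate 1, 4 or 6 (0.0506 to 0.0846; 0.00653 to 0.0846). RT1-DMa lost it with replicate number as a block (0.0534; 0.00103 to 0.0534). Alveolar fluid transport genes rose in 7 and fell in 1 of 14, with Atp1b1 higher (1.42 ± 0.18). Alveolar type 2 genes rose in 5 of 16 (Sftpb 0.69 ± 0.15), surfactant lipid genes rose in 5 and fell in 1 of 18, and alveolar macrophage genes rose in 5 and fell in 1 of 12. Barrier junction genes rose in 3 and fell in 7 of 24. Oxidative phosphorylation genes fell in 5 of 19 (4 adjusted over the list alone) and ribosomal protein genes rose in 2 of 22 (0 adjusted over the list alone).

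The remaining lists held few changed members. Of the cardiac muscle list 4 of 5 fell, the sarcomere genes Tnnt2, Tnni3, Actc1 and Myl4 (5 adjusted over the list alone), of the mesothelium list 2 of 7 fell (Upk1b and Krt19), of the platelet list 2 of 7 rose (Itga2b and Gp6), and of the secretory airway list 1 of 8 rose (Reg3g). In the natural killer, ciliated airway, mast cell and erythroid lists 1 member each fell, namely Tbx21 of 11, Tppp3 of 13, Kit of 10 and Ahsp of 10 (0 for the erythroid list adjusted over the list alone). In the adipose list Adipoq and Cfd fell and the lipase Pnpla2 rose, of 5 (3 fell adjusted over the list alone). Several of these calls rest on Sham replicate 1: without it the log2 changes were 0.11 for Cfd (adjusted p 0.895; 0.0271 to 0.895 over its alternatives), -6.05 for Adipoq (0.139; 8.71e-06 to 0.207), -0.84 for Tnni3 (0.301; 0.00823 to 0.392), -0.95 for Actc1 (0.107; 0.00872 to 0.189) and -0.72 for Myl4 (0.396; 0.0162 to 0.396). Tnnt2 stayed called there at -1.98 instead of -3.31. Cfd was at 246 CPM in Sham replicate 1, 7.05 to 12.3 CPM in the other Sham libraries and 9.56 to 13.9 CPM in CLP, so no fall is seen without that library. Cfd also lost its call without any 1 of the CLP or CLP+VNS libraries or Sham+VNS replicate 1, 3, 4 or 5 (0.0510 to 0.0919). Tnni3 was also lost without CLP replicate 1, 4 or 6 (0.0530 to 0.0663), Actc1 without CLP replicate 4, 5 or 6 (0.0543 to 0.0588), Myl4 without any 1 of the CLP libraries (0.0529 to 0.0692), and Ahsp without Sham replicate 2 or CLP replicate 1, 4 or 6 (0.0512 to 0.0805; 0.00904 to 0.164). The camera adjusted p-values of the 20 uncalled lists ran from 0.0516 (alveolar macrophage) to 0.955 (adipose). The skeletal muscle and liver lists had 2 and 1 tested members and the mitochondrially encoded list none, so these were not tested as lists.

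In all, edgeR called 5955 of 14794 genes between CLP and Sham, 2926 higher and 3029 lower, of which 525 and 646 differed at least 2-fold. Over all tested genes the groups did not overlap for 3862, where chance gives 0.794% of genes. Of these, 3762 were called. Scaled by total count alone, 2341 genes were called higher and 3763 lower, so the balance of the directions depends on the scaling. Of the lists, 16 were called up and 7 down by camera, 7 up and none down with an estimated correlation, and 22 up and 7 down by fry. Leaving out 1 library ended 3 list calls and added 4. The endothelial list was lost without Sham replicate 5 (adjusted p 0.0514; 0.0112 to 0.555 over its alternatives). The NRF2 list was lost without Sham replicate 1 or 4 (0.0624 and 0.0576; 8.87e-06 to 0.140), and the adrenergic list without CLP replicate 5 (0.0511; 0.000212 to 0.266). Added were the alveolar macrophage list without Sham replicate 1 or 3 or CLP replicate 1, 3 or 5 (0.0283 to 0.0467; 0.00547 to 0.447) and the alveolar type 2 list without Sham replicate 2, 3 or 4 or CLP replicate 5 (0.0240 to 0.0472; 0.0201 to 0.563). The platelet list was added without Sham replicate 5 or CLP replicate 5 or 6 (0.0275 to 0.0395; 0.00456 to 0.447), and the alveolar fluid transport list without Sham replicate 2, 3 or 5 or CLP replicate 5 (0.0240 to 0.0485; 0.00153 to 0.404).

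**Figure D3:**
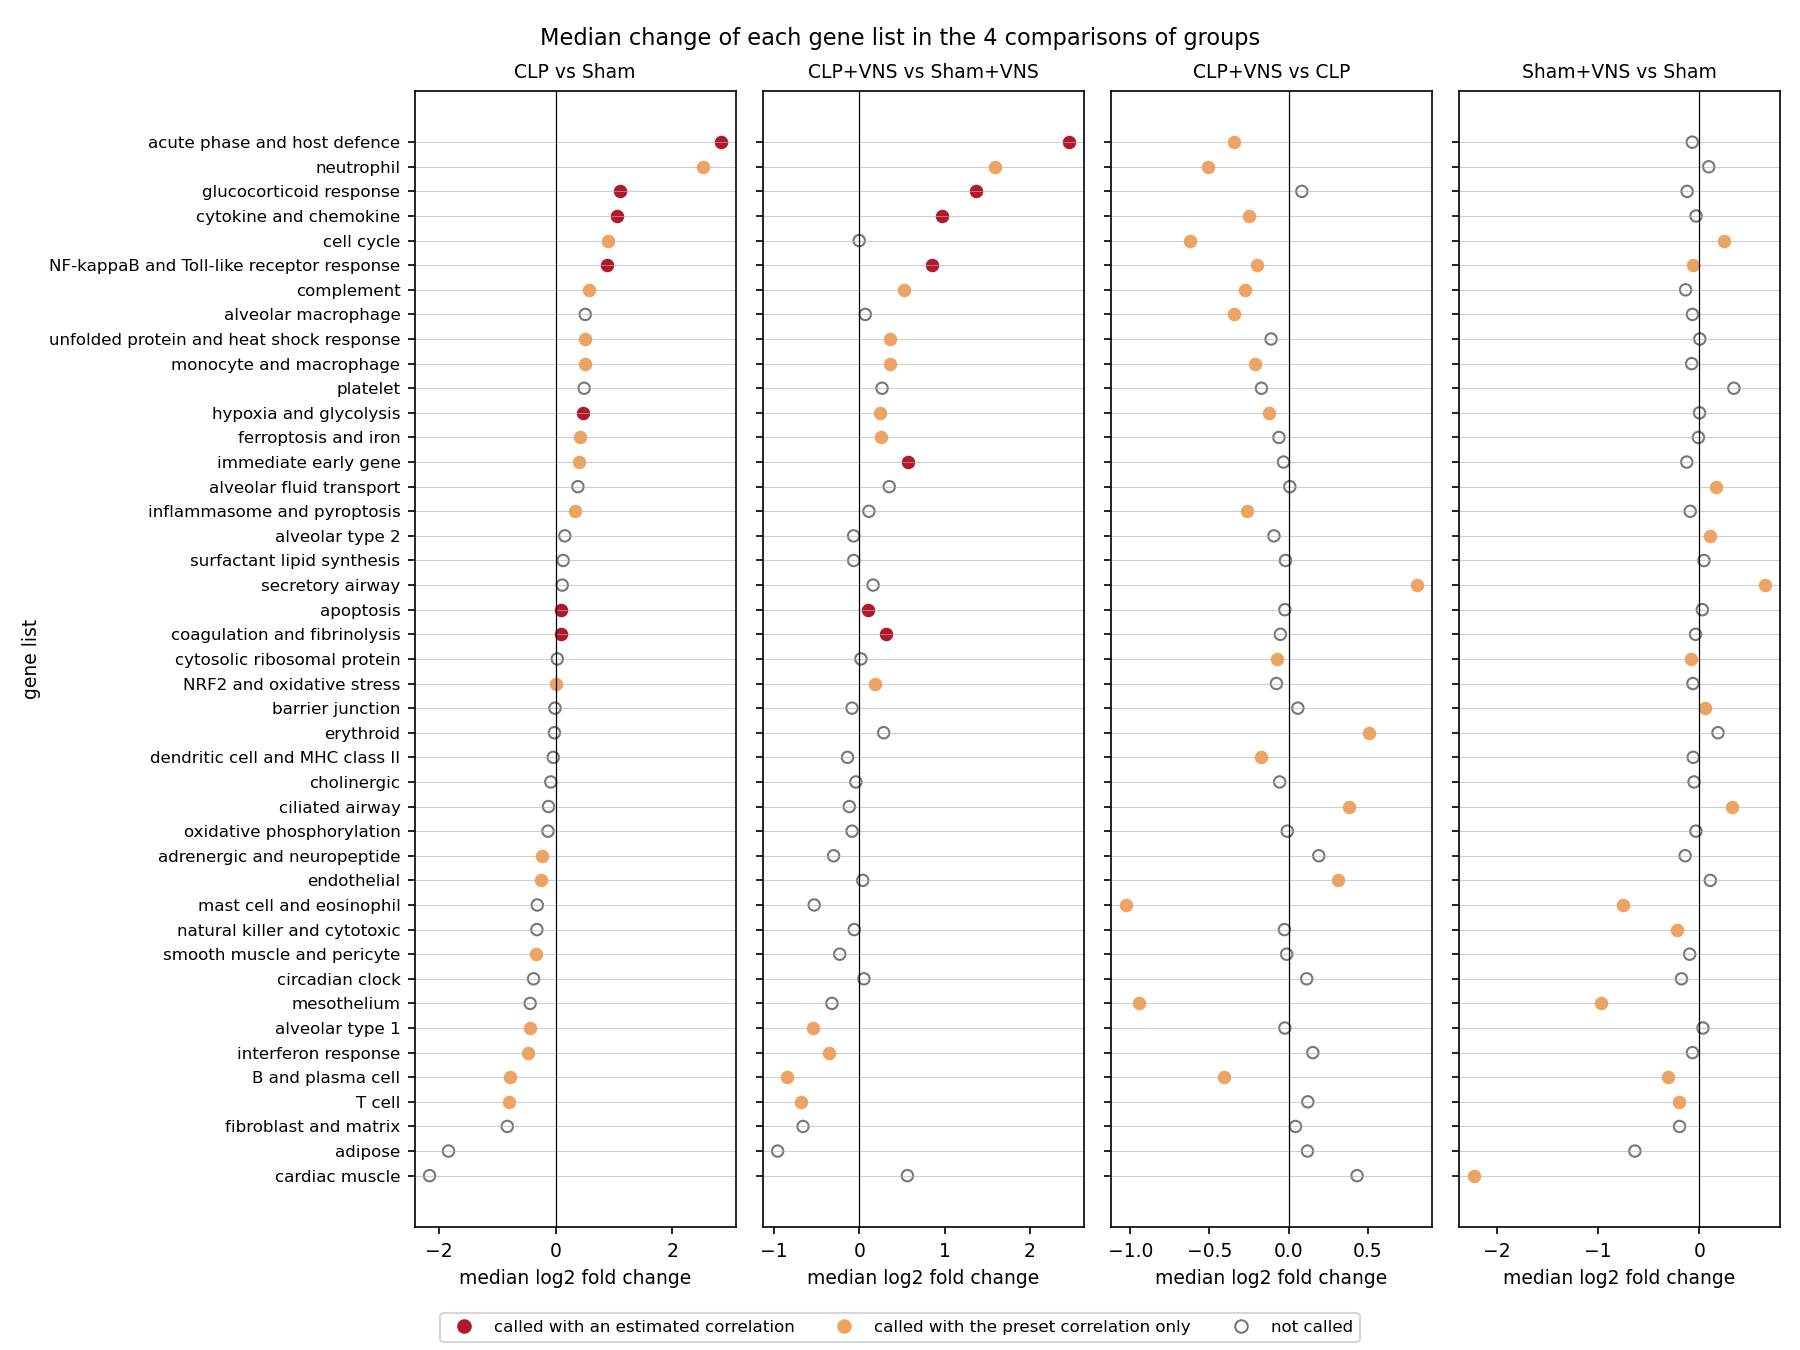
Median log2 fold change of the tested genes of 43 lists in 4 comparisons, each panel with its own horizontal scale; red points are lists called with an estimated correlation, orange points lists called with the preset correlation alone, and open points lists not called. In CLP against Sham 7 lists are red, and in CLP+VNS against CLP and Sham+VNS against Sham none is.

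The comparison of CLP+VNS with Sham+VNS describes the same operation in stimulated animals. The Reg3 genes again stood out: they had no counts in Sham+VNS and were at least 991-fold (Reg3g), 352-fold (Reg3b) and 199-fold (Reg3a) higher in CLP+VNS, at 41.8 ± 27.2, 14.9 ± 10.1 and 8.37 ± 4.74 CPM (n = 5 per group). Fga had a ratio of 195 (66.3 to 948), and Wfdc18 was at least 33.9-fold higher. The protease inhibitor A2m rose by 6.06 ± 0.72 on the log2 scale, Acod1, the enzyme that makes itaconate in macrophages, by 6.01 ± 0.45, Orm1 by 5.67 ± 0.58, Saal1 by 5.44 ± 0.49 and Ngp by 6.13 ± 0.94. The genes that fell most under the naming rule included Mybpc1, at least 38.3-fold lower, Cct6b, a chaperonin subunit (-3.31 ± 0.31), Syt6 (-3.06 ± 0.63), Cntn2 (-2.81 ± 0.29), Krt4, a keratin (-2.79 ± 0.29), Retnlg (-2.72 ± 0.43) and Loxl1, a collagen and elastin crosslinker (-2.53 ± 0.32). Igfbpl1 (-2.97 ± 0.39), the membrane protein Gpm6a (-2.78 ± 0.44) and Ly6al (-6.97 ± 1.96) completed the lower genes. Ly6al was present in some animals of each other group and near 0 in the rest, so its fold depends on which animals fell into the group. Without single libraries Ngp stood at 7.41 (without Sham+VNS replicate 2), Retnlg at -3.57 (without CLP+VNS replicate 11), Syt6 at -3.70 (without CLP+VNS replicate 3), Ly6al at -6.38 (without Sham+VNS replicate 5) and Fga at 8.29 or 6.63 instead of 7.35 (without Sham+VNS replicate 2 or CLP+VNS replicate 1), all still called. Adjusted p-values of these 20 genes ran from 7.53e-08 (Acod1) to 0.0128 (Ly6al). Identifiers not yet given are 24153 (A2m), 306127 (Acod1), 363658 (Cct6b), 315323 (Krt4), 288135 (Retnlg), 315714 (Loxl1), 366366 (Igfbpl1), 306439 (Gpm6a) and 362935 (Ly6al).

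Immune and stress genes of stimulated animals rose after CLP as well. Acute phase genes rose in 18 of 19 cases (median 2.46), NF-kappaB and Toll-like receptor genes in 20 of 28 with 1 lower (0.85), cytokine and chemokine genes in 13 of 23 with 1 lower (0.97), and glucocorticoid response genes in 14 of 16 with 2 lower (1.37). Immediate early genes rose in 10 of 17 (10 up and 2 down adjusted over the list alone), coagulation genes in 7 of 17 with 1 lower, and apoptosis genes in 4 of 15. With an estimated correlation these 7 lists held at adjusted p = 0.0102, 0.00338, 0.00338, 0.00693, 0.0158, 0.0158 and 0.0415. Of the panel, Tnf (2.63 ± 0.25), Il1b (0.97 ± 0.22), Cxcl2 (4.36 ± 0.40), Ccl2 (2.50 ± 0.35), Nfkbia (1.66 ± 0.15), S100a8 (2.88 ± 0.32), Lcn2 (3.86 ± 0.80), Chrna7 (1.91 ± 0.36), Fkbp5 (1.54 ± 0.28) and Per1 (0.86 ± 0.14) rose and Ager fell (-0.52 ± 0.12), with adjusted p-values from 3.12e-07 (Cxcl2) to 0.00386 (Ager). Sftpc (-0.16 ± 0.12, adjusted p = 0.352) and Pecam1 (-0.03 ± 0.11, adjusted p = 0.863) were not called.

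Further lists were called in stimulated animals with the preset correlation alone. Neutrophil genes rose in 15 of 22 with 1 lower (Retnlg), monocyte and macrophage genes in 5 of 17 with 1 lower (the receptor Csf1r), and complement genes in 9 of 19, at adjusted p = 0.237, 0.234 and 0.193 with an estimated correlation. Unfolded protein genes rose in 8 of 16, hypoxia and glycolysis genes in 9 of 19 with Vegfa lower, ferroptosis genes in 5 of 15, and NRF2 genes in 7 of 20 with Sod3 and Gpx1 lower. These 4 gave adjusted p = 0.237, 0.0543, 0.0773 and 0.0773 with an estimated correlation. Adjusted over the list alone the higher members of the complement, unfolded protein, hypoxia, ferroptosis and NRF2 lists numbered 11, 11, 10, 6 and 10, and the lower NRF2 members 3. Gpx1 lost its call without Sham+VNS replicate 3, 4 or 5 or CLP+VNS replicate 5, 8 or 11 (adjusted p 0.0592 to 0.0792; 0.00261 to 0.202 over its alternatives). Alveolar type 1 genes fell in 11 of 15 (Aqp5 -2.01 ± 0.21), T cell genes in 10 of 15 (11 adjusted over the list alone), B cell genes in 6 of 13 (7) and interferon genes in 5 of 30. Those 4 lists gave adjusted p = 0.116, 0.237, 0.505 and 0.764 with an estimated correlation. The cell cycle list was not called here (2 up and 1 down of 20, camera adjusted p = 0.801), nor was the endothelial list (4 up and 6 down of 22, 5 and 6 adjusted over the list alone, camera adjusted p = 0.952). The other uncalled lists had camera adjusted p-values of 0.0696 (inflammasome) and above. In the endothelial, cardiac, adipose, cell cycle, cholinergic, adrenergic, circadian and surfactant lipid lists the median or the mean had another sign than camera's direction, and none of the 8 was called.

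For CLP+VNS against Sham+VNS edgeR called 4044 genes, 2060 higher and 1984 lower, with 366 and 321 at least 2-fold. Over all tested genes the groups did not overlap for 2792, where chance gives 0.794% of genes. Of these, 2629 were called. With total counts alone as the scale 1697 were called higher and 2405 lower. With replicate number as a block the count was 2109, 1135 higher and 974 lower. Of the lists, 14 were called up and 4 down, 7 and 0 with an estimated correlation, and 17 and 4 by fry. The interferon list lost its call without Sham+VNS replicate 2 or 4 (adjusted p 0.0520 and 0.0779) or CLP+VNS replicate 1, 8 or 11 (0.0976, 0.0791 and 0.0948), within 0.00292 to 0.764 over its alternatives. Calls were added for the secretory list without Sham+VNS replicate 2 (0.0355; 0.00764 to 0.702), the smooth muscle list without CLP+VNS replicate 3 or 11 (0.0353 and 0.0397; 0.0353 to 0.712) and the inflammasome list without Sham+VNS replicate 4 or 5 or CLP+VNS replicate 8 (0.0409, 0.0343 and 0.0250; 0.00173 to 0.321). Among the named members of the lists Oas2, an interferon-induced enzyme, lost its call without Sham+VNS replicate 1 or 4 (0.0586 and 0.0950) or CLP+VNS replicate 1, 8 or 11 (0.0756, 0.0676 and 0.0707), within 0.0111 to 0.355.

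The size of the CLP response with and without stimulation was compared across all genes. The slope of the log2 changes in stimulated on those in unstimulated animals was 0.834 with a jackknife SE of 0.101, and 0.762 to 0.872 when single libraries were left out. Across genes, which are not independent replicates, Pearson's r was 0.830 and Spearman's rho 0.760. Of the genes called in both, 3353 had the same sign and 2, Tusc2 and Polk, the opposite sign; 2600 were called in unstimulated animals alone and 689 in stimulated animals alone. In CLP against Sham Tusc2 lost its call without Sham replicate 2, 4 or 5 or CLP replicate 1 or 4 (adjusted p 0.0703 to 0.132; 0.00648 to 0.132 over its alternatives), and Polk without Sham replicate 1, 2 or 4 or CLP replicate 1, 3, 5 or 6 (0.0505 to 0.131; 0.0159 to 0.308). In CLP+VNS against Sham+VNS Tusc2 lost it without Sham replicate 4, Sham+VNS replicate 1, 2 or 4, CLP+VNS replicate 1, 5 or 11 or CLP replicate 1 or 6 (0.0513 to 0.125; 0.0285 to 0.212), and Polk lost it with replicate number as a block (0.104; 0.00486 to 0.104). Being called in 1 arm alone does not show a difference between the arms, which the interaction tests. Under the naming rule Reg3a, Reg3b, Reg3g, Wfdc18, Fga, Orm1, Saal1 and Ngp were among the 10 steepest rises in both arms, and Cntn2, Syt6 and Mybpc1 among the 10 steepest falls.

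**Figure D4:**
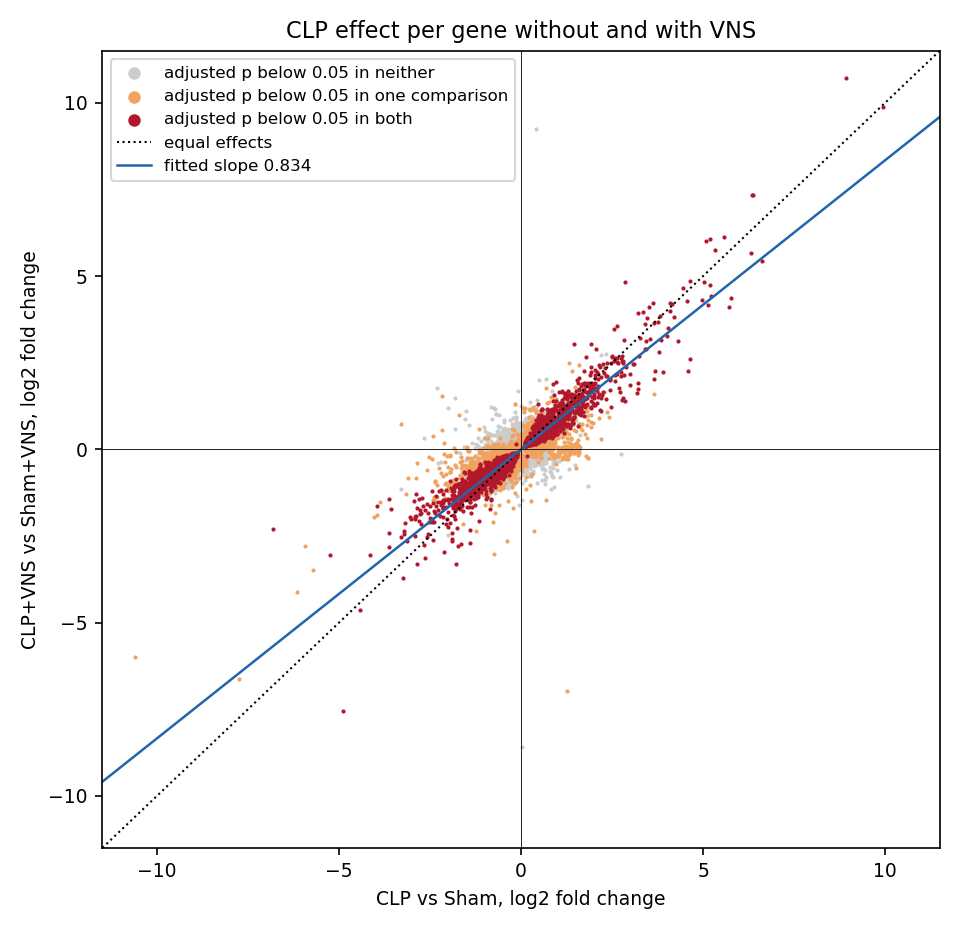
Log2 fold change of CLP+VNS against Sham+VNS (vertical) plotted on that of CLP against Sham (horizontal), 1 point per tested gene, with the fitted line. The slope of the line is 0.834, and of the points called in both comparisons 3353 have the same sign and 2 the opposite sign.

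The comparison of CLP+VNS with CLP asks what stimulation altered in animals with the injury. Il6, the gene of a central fever and acute phase cytokine, was at 0.536 ± 0.0895 CPM in CLP and 0.159 ± 0.0624 CPM in CLP+VNS (37 and 11 counts over the groups, n = 5 each), with no overlap between the groups. The exact two-sided permutation p was 0.00794, the smallest that the 252 regroupings can give, and 0.0317 adjusted over 8 tests. That adjustment leaves out all other genes. Without the count filter, and adjusted over all genes, edgeR called 4 genes between CLP+VNS and CLP, and Il6 was not among them. Il6 was also higher in CLP than in Sham (0.0996 ± 0.0661 CPM; exact p 0.00794, adjusted 0.0317) and in CLP+VNS than in Sham+VNS (0.0280 ± 0.0383 CPM; exact p 0.0159, adjusted 0.0423), while Sham+VNS and Sham gave an exact permutation p of 0.0635 (adjusted 0.114). Il10, the gene of an anti-inflammatory cytokine, was at 0.479 ± 0.219 CPM in CLP and 0.471 ± 0.317 CPM in CLP+VNS (exact permutation p 0.937, adjusted 0.976). Its means in Sham and Sham+VNS were 0.169 ± 0.302 and 0.154 ± 0.124 CPM, and the exact permutation p was 0.119 for CLP against Sham (adjusted 0.159), 0.976 for Sham+VNS against Sham (adjusted 0.976) and 0.0714 for CLP+VNS against Sham+VNS (adjusted 0.114).

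edgeR called 4 genes between CLP+VNS and CLP, each lower with stimulation and without overlap between the groups. Tacc3 (identifier 360962), a protein of the mitotic spindle, went from 23.9 ± 3.33 to 14.4 ± 1.97 CPM (-0.72 ± 0.12). Nckap1l (315348), a subunit of the actin-regulating WAVE complex of blood cells, went from 69.8 ± 4.63 to 49.3 ± 5.33 CPM (-0.50 ± 0.08). Kmt5a (689820), the enzyme that adds a single methyl group to lysine 20 of histone H4, went from 113 ± 7.82 to 88.5 ± 4.98 CPM (-0.35 ± 0.06), and Heatr6 (497972) from 40.2 ± 3.68 to 27.4 ± 2.86 CPM (-0.55 ± 0.09). All 4 had an adjusted p of 0.0421. At an unadjusted p below 0.05 there were 1927 genes, where chance gives 739.7, and 334 genes had groups without overlap, where chance gives 0.794%. DESeq2 called 144 genes (55 higher, 89 lower) and limma 143 (46 higher, 97 lower), 97 of them shared, and both called the 4. The calls depended on single libraries: the count was 277 without CLP+VNS replicate 1 (128 higher, 149 lower, all 4 among them), 0 without CLP+VNS replicate 3, 5 or 8 or CLP replicate 4, 5 or 6, and 1 without CLP+VNS replicate 11 or CLP replicate 3. Where they were lost the 4 genes had adjusted p-values of 0.0740 to 0.149 (2.72e-05 to 0.712 over all alternatives), and Kmt5a alone was lost without CLP replicate 1 (0.0846). Sham-operated libraries, which share the fit's dispersion, also counted: 1 gene was called without Sham replicate 1, 2 without Sham replicate 4, and 0 without Sham replicate 5 or Sham+VNS replicate 1 or 3.

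**Figure D5:**
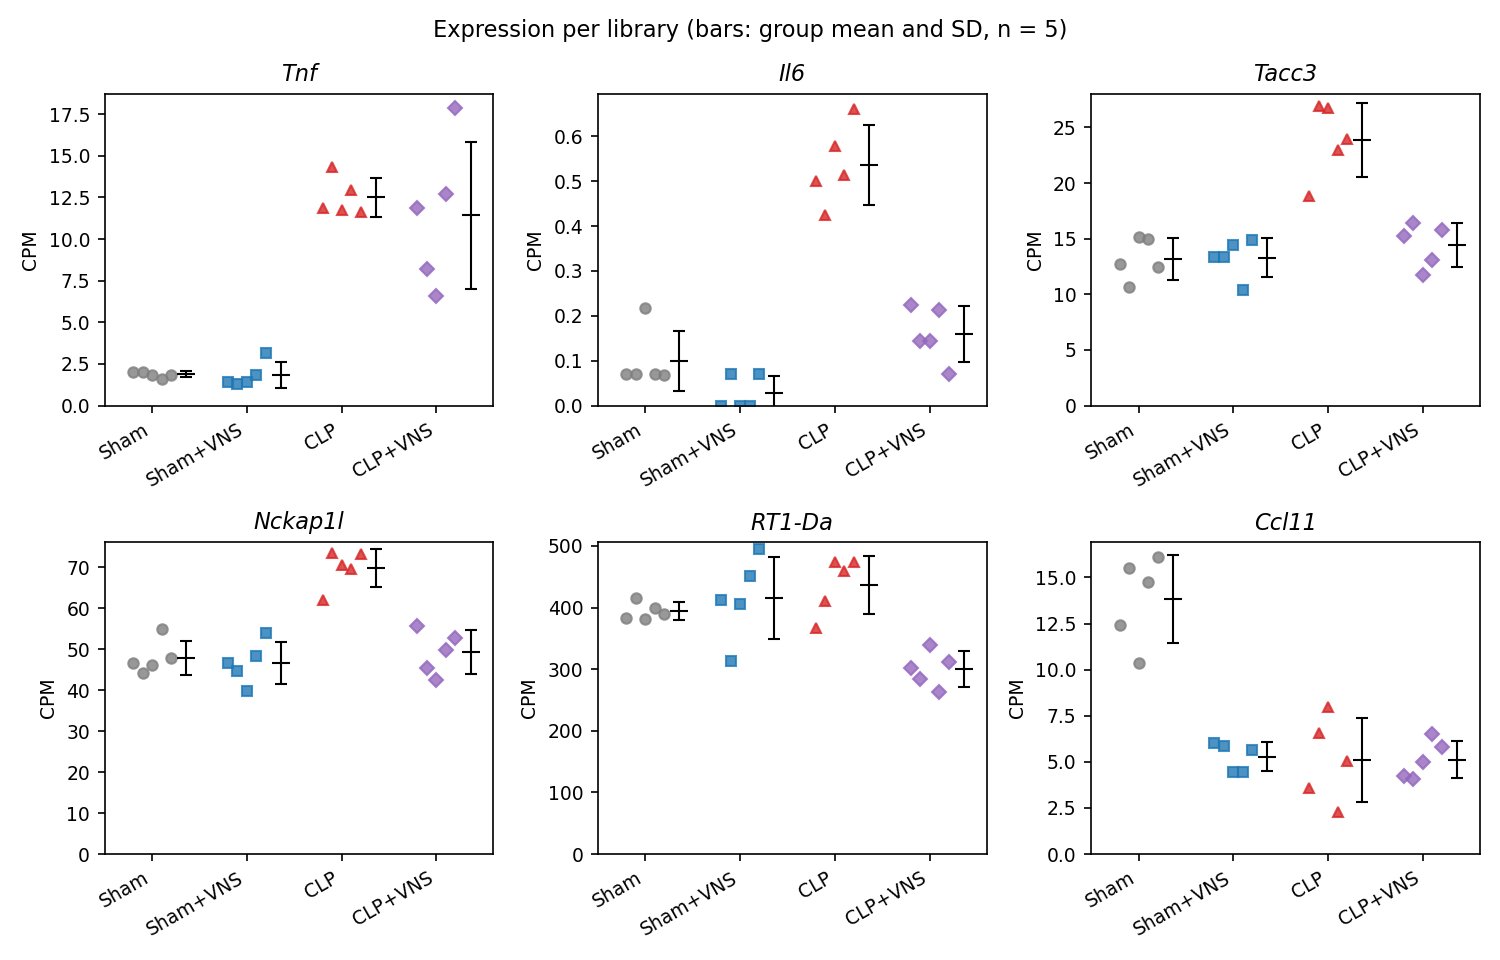
Levels of Tnf, Il6, Tacc3, Nckap1l, RT1-Da and Ccl11 in CPM by group, with points for libraries (5 per group) and bars for the mean ± SD. Il6 lies at 0.536 ± 0.0895 CPM in CLP and 0.159 ± 0.0624 CPM in CLP+VNS, while Tnf is high in both CLP-operated groups.

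Of the panel, no gene was called by edgeR between CLP+VNS and CLP. Log2 differences were -0.13 ± 0.22 for Tnf, -0.26 ± 0.22 for Il1b, -0.28 ± 0.28 for Cxcl2, -0.16 ± 0.31 for Ccl2, 0.13 ± 0.15 for Nfkbia, -0.35 ± 0.30 for S100a8 and -0.40 ± 0.71 for Lcn2. They were -0.09 ± 0.12 for Sftpc, -0.02 ± 0.12 for Ager, 0.31 ± 0.11 for Pecam1, 0.37 ± 0.33 for Chrna7, 0.23 ± 0.27 for Fkbp5 and 0.08 ± 0.14 for Per1, and the adjusted p-values ran from 0.237 (Pecam1) to 0.960 (Ager). Without CLP+VNS replicate 1 Pecam1 was called (0.41, adjusted p 0.0190; 0.0190 to 0.792 over its alternatives), as were 23 more of the named genes of this comparison that were not called with all libraries (0.0114 to 0.0468 over the 24). Without CLP replicate 1 RT1-Da was called (0.0342; 0.000153 to 0.712).

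Several gene lists shifted between CLP+VNS and CLP under camera with the preset correlation, and none held with an estimated correlation. No member of a list was called over all genes, so member counts here are adjusted over the list alone. Endothelial genes were higher with stimulation, 14 of 22 (median 0.31; adjusted p = 0.108 with an estimated correlation), with Aplnr at 0.63 ± 0.13, Egfl7 at 0.40 ± 0.10, Ramp2 at 0.48 ± 0.13 and Emcn at 0.55 ± 0.15. Cell cycle genes were lower, 13 of 20 (median -0.62; adjusted p = 0.204 with an estimated correlation), with the transcription factor Foxm1 at -0.60 ± 0.14 and the ribonucleotide reductase subunit Rrm2 at -0.99 ± 0.23. NF-kappaB and Toll-like receptor genes were lower in 7 of 28 (median -0.20), with Nfkb2 at -0.23 ± 0.06 and Zc3h12a at -0.36 ± 0.10. Dendritic cell and MHC class II genes were lower in 7 of 17 (median -0.17), with the class II chain RT1-Da at -0.54 ± 0.10 and the invariant chain Cd74 at -0.42 ± 0.10; RT1 class II genes can share reads. Cytokine and chemokine genes were lower in 3 of 23 (median -0.25), with Cxcl16, a chemokine and scavenger receptor, at -0.35 ± 0.06. These last 3 lists each gave adjusted p = 0.0644 with an estimated correlation. Neutrophil genes had a median of -0.51 with 0 of 22 members passing, at adjusted p = 0.242 with an estimated correlation. By fry the endothelial list was higher (adjusted p 0.0277) and the NF-kappaB, MHC class II and cytokine lists lower (0.0105 each). These 6 lists had camera adjusted p-values from 3.87e-13 (endothelial) to 0.00175 (cytokine).

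A further 13 lists were called between CLP+VNS and CLP with the preset correlation. Lower with stimulation were complement (median -0.27, 2 members, Cfp and C5ar1), alveolar macrophage (-0.35, 1, the scavenger receptor Olr1), mesothelium (-0.94, 0), ribosomal protein (-0.07, 0), mast cell and eosinophil (-1.03, 1, the mast cell protease Mcpt2 at -2.24 ± 0.49) and acute phase genes (-0.34, 0). Also lower were monocyte and macrophage (-0.21, 0), hypoxia and glycolysis (-0.12, 4: Pkm, Gapdh, Pgk1 and Eno1), inflammasome (-0.26, 3: Nlrp3, Il18 and Nlrc4) and B cell genes (-0.41, 0), the second number being members that pass adjusted over the list alone. Higher were ciliated airway (0.38), erythroid (0.51) and secretory airway genes (0.81), with no single member passing. Camera's adjusted p-values ran from 0.000131 (ciliated) to 0.0230 (B cell), and with an estimated correlation from 0.242 to 0.535. The secretory list was lost without CLP+VNS replicate 3 (adjusted p 0.0752; 0.00221 to 0.413 over its alternatives), the B cell list without CLP+VNS replicate 1 or 3 or CLP replicate 3 or 5 (0.0938, 0.116, 0.247 and 0.248; 0.000440 to 0.535), the inflammasome list without CLP+VNS replicate 8 (0.0709; 0.00173 to 0.242) and the hypoxia list without CLP replicate 3 (0.0517; 0.000968 to 0.242). Calls were added for 7 lists. These were alveolar type 1 without CLP replicate 5 (0.0332; 0.0332 to 0.931), alveolar type 2 without CLP+VNS replicate 1, 5 or 8 or CLP replicate 5 (0.0139 to 0.0457; 0.0139 to 0.557), smooth muscle without CLP+VNS replicate 1 or CLP replicate 3 (0.00870 and 0.0350; 0.00870 to 0.954) and barrier junction without CLP+VNS replicate 1 (0.0462; 0.0462 to 0.515). The others were interferon without CLP+VNS replicate 1, 8 or 11 or CLP replicate 3 or 4 (0.00329 to 0.0209; 1.52e-05 to 0.771), unfolded protein without CLP+VNS replicate 1 or 5 or CLP replicate 3 or 4 (0.00811 to 0.0446; 0.00811 to 0.565) and adrenergic without CLP+VNS replicate 1 or CLP replicate 3 or 4 (0.00758 to 0.0446; 0.00758 to 0.413). With all libraries the other 24 lists were not called; of them NRF2 had 3 lower members, smooth muscle 2 higher (Pdgfrb and Notch3) and apoptosis 1 lower (Bcl2a1), adjusted over the list alone. In the smooth muscle, cardiac and coagulation lists the median or mean had another sign than camera's direction.

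The changes with stimulation were set against those of CLP itself, which share the CLP libraries with opposite signs. All 4 called genes had risen in CLP against Sham and were lower in CLP+VNS, where independent lists would give 0.791 opposite calls. Tacc3 had changed by 0.86 ± 0.12 with CLP, Nckap1l by 0.54 ± 0.08, Kmt5a by 0.25 ± 0.06 and Heatr6 by 0.64 ± 0.09. At an unadjusted p below 0.05 in CLP+VNS against CLP, 928 genes called with CLP moved the opposite way and 119 the same way. In 20 simulations with a CLP effect and no effect of stimulation, sharing the CLP libraries gave a median of 220 opposite (195 to 253) and 84 same. The simulated genes varied independently of one another. Their range therefore leaves out differences that many genes of a library share, and it cannot decide whether 928 exceeds chance. When the CLP libraries were divided so that none served both comparisons, 20 divisions gave a median of 433.5 opposite (260 to 684) and 91 same. Each comparison then had fewer CLP libraries, so lower counts there can come from lower power. The covariance of the log2 changes was -0.0626 as observed, -0.0270 in the simulations (median) and -0.0410 in the divisions (-0.0620 to -0.0271). The count of opposite calls was 202 without CLP+VNS replicate 1, 2 without Sham replicate 4, 1 without Sham replicate 1, CLP+VNS replicate 11 or CLP replicate 3, and 0 without Sham replicate 5, CLP+VNS replicate 3, 5 or 8 or CLP replicate 4, 5 or 6. It was not taken without Sham+VNS libraries, but without Sham+VNS replicate 1 or 3 no gene was called between CLP+VNS and CLP.

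The comparison of Sham+VNS with Sham describes stimulation without the injury. No gene was called by edgeR, with 1185 at an unadjusted p below 0.05 where chance gives 739.7; DESeq2 called 6 and limma 1. The gene with the smallest p was Ccl11, the eosinophil chemoattractant eotaxin (identifier 29397), at 13.8 ± 2.39 CPM in Sham and 5.28 ± 0.780 CPM in Sham+VNS (-1.39 ± 0.24, adjusted p = 0.176, n = 5 per group), which did not pass the threshold. The next 4, also not past it, were the mitochondrial ribosomal protein Mrps34 (287126; -0.41 ± 0.08), the noradrenaline transporter Slc6a2 (83511; 0.97 ± 0.20), Gcsam (685692; -0.53 ± 0.11) and Pianp (312711; -1.71 ± 0.37), with adjusted p-values of 0.405 for Mrps34 and 0.485 for the others. Of the panel, Nfkbia was at -0.47 ± 0.15, Fkbp5 at 0.70 ± 0.28, Per1 at -0.37 ± 0.14 and Cxcl2 at 1.12 ± 0.64, and none passed. The groups did not overlap for 118 of the 14794 tested genes, about the 0.794% that chance gives. Without Sham replicate 3 edgeR called 2 genes.

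Of the lists, 14 were called between Sham+VNS and Sham with the preset correlation, with adjusted p = 0.667 to 0.713 with an estimated correlation, and fry called none. Higher were ciliated airway (median 0.32), secretory airway (0.65), alveolar type 2 (0.10), alveolar fluid transport (0.16), cell cycle (0.24) and barrier junction genes (0.05). Lower were cardiac muscle (-2.23), mesothelium (-0.97), mast cell and eosinophil (-0.75), B cell (-0.31), natural killer (-0.22), T cell (-0.20), ribosomal protein (-0.08) and NF-kappaB genes (-0.06). No member passed over all genes; adjusted over the list alone 4 of 5 cardiac genes did (Myl4, Tnnt2, Tnni3 and Actc1, all lower), 3 NF-kappaB genes (Sele, Cebpd and Nfkbia, lower), 1 mesothelial gene (Upk3b, lower, at 261 CPM in Sham replicate 1 and 41.8 to 101 CPM in the other Sham libraries) and 1 alveolar type 2 gene (Sftpd, higher). In the uncalled glucocorticoid list 1 member was higher (Zbtb16) and 4 lower (Cebpd, Ddit4, Per1 and Nr3c1), and in the uncalled cytokine list 1 was higher (Cxcl3), adjusted over the list alone. Without Sham replicate 1 the mesothelium list went to an adjusted p of 0.524 (0.000296 to 0.667 over its alternatives) and the mast cell list to 0.355 (5.11e-05 to 0.667). The T cell (0.398), barrier junction (0.489), alveolar type 2 (0.150), secretory airway (0.0905), cell cycle (0.0905) and alveolar fluid transport lists (0.0667) were lost there too, within 1.85e-05 to 0.799 over the alternatives of these 6. Without Sham+VNS replicate 3 the natural killer (0.218; 4.83e-05 to 0.668), B cell (0.0542; 6.52e-05 to 0.667) and NF-kappaB lists (0.0523; 0.000401 to 0.667) were lost, and with them the T cell (0.625), cell cycle (0.494), barrier junction (0.184) and mesothelium lists (0.0567). The ciliated, cardiac and ribosomal lists kept their calls without each single library, but without Sham replicate 1 the cardiac median was -0.90 instead of -2.23, with Tnnt2 at 24.6 CPM in that library and 1.05 to 7.32 CPM in the other Sham libraries. There the medians of the mesothelium and mast cell lists were -0.21 and -0.09, and the secretory median was -0.08 without Sham+VNS replicate 2, which ended its call (0.275). Genes of the cardiac list are also known from the sleeve of heart muscle around the pulmonary veins of rodents. Camera called none of the other 29 lists, and in the coagulation and hypoxia lists, as in the cytokine list, signs of median, mean and test differed.

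The interaction asks whether the effect of stimulation differed between CLP-operated and sham-operated animals. No gene was called by edgeR (smallest adjusted p = 0.50), with 1217 at an unadjusted p below 0.05; DESeq2 called 6 (2 higher, 4 lower) and limma none. The 5 smallest p-values, none past the threshold, were those of Cep55, a protein of the final step of cell division (294074; -2.08 ± 0.45), Cpne7 (361433; 2.69 ± 0.58), RT1-Da (294269; -0.62 ± 0.14), Ccdc28a (361454; -0.49 ± 0.11) and Sptssa, a subunit of the enzyme that starts sphingolipid synthesis (500651; 0.36 ± 0.08). Of the panel, Nfkbia was at 0.61 ± 0.21, Cxcl2 at -1.40 ± 0.70 and Per1 at 0.45 ± 0.20, with no call. Among the lists camera called 5 up and 12 down with the preset correlation. Cell cycle genes had the most negative median of those called down (-0.95; 12 of 20 lower adjusted over the list alone, adjusted p = 0.473 with an estimated correlation), and neutrophil genes a median of -0.59 (adjusted p = 0.473 with an estimated correlation). Endothelial genes (median 0.23) and interferon genes (0.18) were among those called up, at adjusted p = 0.473 and 0.731 with an estimated correlation. None of the 17 held with an estimated correlation and fry called none. In the cell cycle list Mki67 was uneven within groups. It was high in CLP replicates 4, 5 and 6 alone of the CLP animals. Of the Sham+VNS animals replicates 3 and 5 were highest, at 34.6 and 28.0 CPM. The edgeR count was 3 without CLP+VNS replicate 1.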

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

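The tests of a lower leukocyte share, of exchanged labels, of tissue other than lung and of allele copies, and leaving out the libraries with Adipoq above 5 CPM, were chosen only after the result was seen. Single libraries are listed here where the gap to the nearest library of the same group, divided by the range of the group, exceeded Dixon's 95% critical value for 5 values, which chance alone gives in about 1 of 20 groups. This held for 0 of 4 groups for total count (0.2 expected), 7 of 52 for panel genes (2.6 expected), 14 of 180 for list scores (9 expected) and 19 of 168 for other named genes (8.4 expected). Sham replicate 1 was listed 9 times, Sham replicate 3 5 times and CLP+VNS replicate 11 4 times.

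In Sham replicate 1 the values set apart were Sftpc at 9550 CPM, Wfdc18 at 0.141, Fga at 0.282, Tm4sf4 at 37.8, Mybpc1 at 10.1, Esr1 at 15.3 and Gcsam at 10.5 CPM, a mast cell list score of 4.43 and an oxidative phosphorylation score of 6.88 (scores in log2 CPM). In Sham replicate 3 they were Reg3b at 0.0726 CPM, Orm1 at 1.31, Cpvl at 1.74 and Fam151a at 0.726 CPM and a smooth muscle score of 5.02. Sham replicate 5 had an MHC class II score of 4.88, an adrenergic score of 2.96 and Slc6a2, a noradrenaline transporter of sympathetic nerves and lung endothelium, at 56.4 CPM. Slc6a2 was also set apart in Sham+VNS replicate 1 (105 CPM) and CLP replicate 5 (73.9 CPM). Tnf reached 3.17 CPM and Cxcl2 0.282 CPM in Sham+VNS replicate 5. The other Sham+VNS libraries had Cxcl2 at 0.206 to 0.214 CPM, so that gap lies near the count floor. So do the gaps of Wfdc18, Fga and Reg3b, with 2, 5 and 1 counts over the Sham group. S100a8 was at 66.6 CPM and the acute phase score at 3.38 in Sham+VNS replicate 3. Sham+VNS replicate 2 had Sftpc at 10600 CPM, Ngp at 0.626 CPM and a mast cell score of 3.34, and Sham+VNS replicate 4 a cardiac muscle score of -0.241. In CLP replicate 3 Il1b was at 77.6 and Ngp at 52.4 CPM, in CLP replicate 5 Saal1 at 248 CPM, and in CLP replicate 1 Adh7 at 2.79 CPM with an erythroid score of 5.02. CLP+VNS replicate 1 had Pecam1 at 360 CPM. CLP+VNS replicate 11 had alveolar macrophage and mesothelium scores of 4.73 and 4.87, Pianp at 2.74 CPM and Retnlg at 3.02 CPM. CLP+VNS replicate 3 had a cardiac muscle score of 1.96, and CLP+VNS replicate 5 a coagulation score of 5.18 and a surfactant lipid score of 6.69.

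Camera with the preset correlation called 17 lists in the interaction, but none held with an estimated correlation (adjusted p = 0.473 to 0.731) and fry called 0, so these list calls rest on the preset correlation. With the preset correlation the lists called lower were the cell cycle (adjusted p 8.76e-13), neutrophil (4.3e-07), alveolar type 2 (0.000137), alveolar macrophage (0.0113), MHC class II (0.0113), acute phase (0.0113), NF-kappaB (0.0265), cytokine (0.0353), surfactant lipid (0.0356), hypoxia (0.0442), platelet (0.0457) and unfolded protein lists (0.0493). The MHC class II median, -0.0282, turned positive (0.0130 to 0.0920) without Sham replicate 4, Sham+VNS replicate 2 or 4, CLP+VNS replicate 8 or CLP replicate 3 or 5. The lists called higher were the endothelial (1e-05), cardiac muscle (0.0113), adrenergic (0.0351), interferon (0.0356) and smooth muscle lists (0.0442). The cardiac median was 1.40 without Sham replicate 1 and 2.10 without CLP+VNS replicate 3, instead of 2.74. In the cell cycle list Foxm1 stood at -0.64 ± 0.20 and Rrm2 at -0.95 ± 0.33 on the log2 scale, and in the endothelial list Aplnr at 0.71 ± 0.18.

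The transcript table was not part of the gene comparisons. In CLP against Sham 12 genes with a mean of at least 5 CPM had 1 transcript called higher and another called lower, and for 11 of the 12 the directions were the same in CLP+VNS against Sham+VNS, Il6st being the exception. Transcripts of Mettl9, a histidine methyltransferase, were at 2.76 ± 0.35 and -0.95 ± 0.18 on the log2 scale, those of Il6st, the shared receptor chain of the interleukin 6 family, at 0.71 ± 0.22 and -2.19 ± 0.49, and those of Grk6, a receptor kinase, at 0.56 ± 0.12 and -0.85 ± 0.17. Aoc1, a diamine oxidase, had a transcript that went from 6.45 to 106 CPM and another that went from 16.8 CPM to 0 counts.

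The 1927 genes at an unadjusted p below 0.05 between CLP+VNS and CLP may come from stimulation, from the make-up of the lung pieces or from labels. A lower share of leukocytes with the other cells alike needs the endothelial score minus the mean alveolar score to differ by less than 0.2. That score was -1.37 ± 0.0591 in CLP and -1.03 ± 0.216 in CLP+VNS, a difference of 0.346 (exact two-sided permutation p 0.0238, n = 5 per group). The test was chosen when endothelial genes were already seen to be higher, so its outcome could be foreseen and no conclusion is drawn from it. It does not measure leukocytes, so a lower leukocyte share beside other changes stays open. Different amounts of airway and blood cannot be told apart from an effect of stimulation. With the ciliated and erythroid scores as covariates 1227 genes were below 0.05, 960 of them among the 1927, and edgeR called 0. DESeq2 and limma were not run with these covariates. On the axis from CLP (0) to CLP+VNS (1) CLP+VNS replicate 1 lay at 0.0720 and CLP replicate 3 at 0.548, with the other CLP libraries at 0.0425 to 0.528 and the other CLP+VNS libraries at 0.537 to 0.998, so an exchange of these 2 labels, with which edgeR calls 219 genes, is neither excluded nor shown, and a single wrong label needs no partner. An effect of stimulation stays open as a hypothesis.

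The adipose genes of Sham replicate 1 may come from tissue other than lung, since 4 of the 5 tested list members had their highest value of the 20 libraries there (Adipoq 285, Cfd 246, Lpl 469 and Cidea 50.6 CPM). Adipoq was also at 9.72 CPM in Sham replicate 2, 96.3 in Sham+VNS replicate 2 and 16.2 in Sham+VNS replicate 4, and at most 1.29 CPM in the other 16 libraries; Lpl, Cfd and Pnpla2 are expressed in lung as well. Such tissue as the source of the genes called lower in CLP is argued against, because 76.0% of them (2302 of 3029) stayed called lower without those 4 libraries, as 78.9% of the higher ones did, and all 10 named lower genes did, though with smaller log2 changes for Tm4sf4 (-4.26 instead of -5.93), Mybpc1 (-3.84 instead of -4.90) and Esr1 (-2.58 instead of -3.63). No biological explanation was tested.

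The levels of 11 genes fell into separate steps across animals within groups, with a gap of at least 3 on the log2 scale. Animals with 0, 1 or 2 copies of an allele are a candidate explanation: among libraries above the gap, the ratio of the 2 levels had a median of 1.99 (1.13 to 2.75). The libraries below the gap still reached 8.23 CPM for LOC100362027, 7.65 CPM for Dstnl1 and 6.56 CPM for H3f3c, a level that 0 copies does not describe. Reads moved to or from a near-identical copy cannot be told apart for 3 of the 11, whose partner gene fell as they rose. These are H3f3c and, as each other's partner, Rpl30 and LOC100362027. Rpl30 was at 109.6 to 272 CPM in 15 libraries. In the rest it was at most 0.0735 CPM and LOC100362027 at 217 to 264 CPM. Ly6al was high in 9 of the 15 libraries outside CLP+VNS (24.8 to 133 CPM) and in 0 of 5 in CLP+VNS. It was chosen for this pattern, so no test on it can support that.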

How the results depend on the processing

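Leaving out the 4 libraries with Adipoq above 5 CPM was chosen after seeing the data, all others before. The counts for CLP against Sham (4732 to 6194 over the other settings with all libraries) and for CLP+VNS against Sham+VNS kept within 1.5 times except at a 2-fold threshold (1171 and 687, fewer by construction) and, for the latter, with replicate number as a block (2109). Of 17 libraries with a partner of equal number 4 correlated best with it, which cannot exclude pairs. The slope was 0.762 to 0.931. For CLP+VNS against CLP the count of 4 became 0 at a 2-fold threshold, with upper quartile factors, with total count alone, with the 2 groups alone, with the block and with the deposited FPKM at either pseudocount, 144 with DESeq2, 143 with limma and 7 without the Adipoq libraries, and ranged from 0 to 277 without single libraries. For Sham+VNS against Sham the count of 0 became 6 with DESeq2, 1 with limma and 1 with the 2 groups alone, and 0 to 2 without single libraries. The interaction's 0 became 6 with DESeq2 and 0 to 3 without single libraries. The 4 opposite calls became 97 with DESeq2, 0 with the block, 928 at unadjusted p below 0.05 (a looser threshold by construction) and 0 to 202 without single libraries. For the other moves the cause was not tested.

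With an estimated correlation the list calls were 7 for CLP against Sham, 0 for CLP+VNS against CLP, 0 for Sham+VNS against Sham, 7 for CLP+VNS against Sham+VNS and 0 for the interaction. What lowered these counts was not tested. By fry, which tests another hypothesis, 4 were called for CLP+VNS against CLP, 0 for Sham+VNS against Sham and 0 for the interaction. Without the Adipoq libraries 9 were called for Sham+VNS against Sham and 11 for the interaction. Leaving out single libraries gave 8 to 19 list calls for Sham+VNS against Sham (9 without Sham replicate 1, 8 without Sham+VNS replicate 3) and 11 to 22 for the interaction (11 without Sham replicate 2 or CLP+VNS replicate 3 or 5). Of the 14 Sham+VNS calls 11 were lost without some library: 8 without Sham replicate 1 (adjusted p 0.0667 to 0.524), 1 without Sham replicate 2 (0.0593), 4 without 3 (0.0939 to 0.124), 3 without 4 (0.107 to 0.144) and 1 without 5 (0.171). Without Sham+VNS replicate 1 the losses were 2 (0.0624 to 0.0855), without 2 also 2 (0.0776 to 0.275), without 3 they were 7 (0.0523 to 0.625), without 4 it was 1 (0.0672) and without 5 also 1 (0.218). Calls were added for 14 other lists: without Sham replicate 1 to 5 in turn 2 (0.0152 to 0.0172), 1 (0.00922), 2 (0.0379 to 0.0408), 6 (0.0177 to 0.0492) and 2 (0.0124 to 0.0177), and without Sham+VNS replicate 1 to 5 in turn 2 (0.00542 to 0.0312), 1 (0.0427), 1 (0.0397), 2 (0.0273 to 0.0324) and 6 (0.00175 to 0.0485). Of the 17 interaction calls 11 were lost: 7 without Sham replicate 2 (0.0567 to 0.722), 6 without Sham+VNS replicate 2 (0.0584 to 0.294), 9 without CLP+VNS replicate 3 (0.0592 to 0.296), 7 without CLP+VNS replicate 5 (0.0502 to 0.224), 5 without CLP replicate 5 (0.0544 to 0.249) and 1 to 4 without each of the other 15 (0.0504 to 0.244). Calls were added for 11 lists, 6 of them without Sham replicate 1 (0.00107 to 0.0464), 5 without Sham+VNS replicate 1 (0.00725 to 0.0456) and at most 3 without each other library. The circadian clock list turned between CLP+VNS and CLP with the block (adjusted p 0.0263; 0.0263 to 0.996 over its alternatives), and for Sham+VNS against Sham the neutrophil list turned without the Adipoq libraries (0.0144; 0.0144 to 0.911) and the adipose list without Sham replicate 1 (0.00904, against up to 0.950 without other single libraries); the cause was not tested.

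Over all alternatives the named genes kept their side of the threshold in 2654 of 2661 cases for CLP against Sham and 1964 of 2085 for CLP+VNS against CLP. They did so in 1666 of 1673 for Sham+VNS against Sham, 2159 of 2179 for CLP+VNS against Sham+VNS and 2648 of 2651 for the interaction. Direction was checked only where a gene was called in the main or the alternative fit. In the main fit 4 of 91 named genes were called for CLP+VNS against CLP. For Sham+VNS against Sham it was 0 of 73 and for the interaction 0 of 83. In these comparisons most cases therefore tell nothing about direction. Depth left Il6 and Il10 under the count filter.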

Other observations

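The regroupings of libraries were planned, and the genes named in the next paragraphs were chosen only after their values were seen. Genes that DESeq2 and limma both called between CLP+VNS and CLP (97, of which edgeR called 4) were higher with stimulation in 32 cases and lower in 65, and no list test was run on them. Examples of the lower genes are the transcription factor Spi1 (-0.42 ± 0.09), the integrin chains Itgal (-0.49 ± 0.11) and Itgb2 (-0.52 ± 0.14), the Fc receptor chain Fcer1g (-0.40 ± 0.09), the adaptor Tyrobp (-0.39 ± 0.10), the phosphatase Ptprc (-0.42 ± 0.10) and the oxidase subunit Cyba (-0.36 ± 0.09). Sod2 (-0.52 ± 0.12), Nlrp3, the sensor of an inflammasome (-0.57 ± 0.13), and progranulin, Grn (-0.53 ± 0.11), were lower too. Examples of the higher genes are Aplnr (0.63 ± 0.13), Clec14a (0.37 ± 0.09), the hypoxia factor Epas1 (0.34 ± 0.10), the receptor Pdgfrb (0.40 ± 0.09), the transcription factors Foxf2 (0.56 ± 0.13) and Tbx5 (0.50 ± 0.11), and the guanylate cyclase subunits Gucy1a1 (0.36 ± 0.08) and Gucy1b1 (0.38 ± 0.10). edgeR called none of these 18 over all genes. Other kinds of genes were among the 97 as well, such as Eloa, Xylt1, Gapdh and Pkm lower and Fads2, Prnp, Unc5a and Epb41 higher. Of the 97, 86 were called also by edgeR without CLP+VNS replicate 1.

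Among clock genes, the repressor genes Per3 (-1.44 ± 0.33) and Nr1d1 (-1.25 ± 0.34) were lower in CLP than in Sham, and Npas2, a partner of Arntl, was higher (1.78 ± 0.46). The hour of collection is not given, so its part in these differences cannot be told apart from that of CLP. Without the 4 libraries with Adipoq above 5 CPM Nr1d1 and Npas2 were not called (adjusted p 0.0583 and 0.0619; 0.000514 to 0.0583 and 0.000605 to 0.0619 over their alternatives). Dbp went from 106 ± 39.7 to 14.4 ± 9.10 CPM and Arntl from 10.6 ± 3.96 to 45.6 ± 12.7 CPM (mean ± SD, n = 5 per group). In CLP+VNS they were at 19.0 ± 22.1 and 51.9 ± 21.0 CPM, with CLP+VNS replicate 8 at 57.4 CPM for Dbp and 21.1 CPM for Arntl. Barrier genes went both ways after CLP, with the junction molecule Jam2 higher (0.90 ± 0.11) and the vessel-stabilizing factor Angpt1 lower (-1.07 ± 0.13). Among neuropeptide receptors Tacr1, the substance P receptor, rose (3.64 ± 0.71; 4.80 without Sham replicate 3 and 2.80 without CLP replicate 5) and Vipr2 fell (-1.12 ± 0.18). The metallothionein Mt2A rose (5.19 ± 0.53), as did the matrix crosslinker Lox (1.80 ± 0.16).

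Chance was weighed by counting how many of 100 regroupings of the libraries, the real one included, called at least as many genes. For CLP against Sham 1 of the 100 did, the real one, with 5955 genes against 1547 in the highest other. None of the other regroupings drawn reached the real count, so chance is an unlikely source, though not all regroupings were drawn. For CLP+VNS against Sham+VNS it was again 1, with 4044 against 264. For CLP+VNS against CLP it was 3 of 100, with 4 genes against 113 in the highest other. For genes at an unadjusted p below 0.05 it was also 3, with 1927 against 2349. That share is small among the regroupings drawn. Not all regroupings were drawn, however, and 1 outside the 100 went higher still, so chance is not excluded. An exchange of CLP+VNS replicate 1 and CLP replicate 3, looked at apart from the 100 and not among them, called 219 genes with 2717 below 0.05. The highest of the 100 exchanged CLP+VNS replicate 1 and CLP replicate 1 and called many times the real count, which points to a structure of the samples. For Sham+VNS against Sham all 100 called at least the real 0, as they must, so that count tells nothing. The highest other called 179, exchanged Sham replicate 3 and Sham+VNS replicate 4 and points to a structure too. At an unadjusted p below 0.05, 21 of 100 reached the real 1185 (2328 in the highest other), so chance cannot be excluded. In the interaction all 100 again called at least the real 0 by construction, with 4 in the highest other, and 9 of 100 reached the real 1217 at an unadjusted p below 0.05 (1865 in the highest other), so chance cannot be excluded there either.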
